A study of Mus musculus with 96 samples.

How the data were processed

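Single mouse embryonic stem (ES) cells of the J1 line, a male line from strain 129 mice, were grown without feeder cells in serum and leukaemia inhibitory factor (LIF), per the labels' protocols. Cells were captured on a microfluidic chip, their cDNA was amplified on the chip with the SMARTer kit, and Nextera XT libraries were sequenced on an Illumina HiSeq, per the labels' protocols. The kit does not mark the strand of the transcript, so reads of a gene and of its antisense partner cannot be told apart. Each of the 48 cells was sequenced on 2 lanes, which gave 96 samples. The values are whole-number read counts per gene, deposited by the authors as a single table of 23284 gene rows with no normalization. The submitters' processing notes name STAR 2.3.1z12, featureCounts, Subread 1.4.5-p1 and the genome build mm9, with no role or order. Every column matched 1 sample by its label.

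All cells belong to a single group. The labels name no separate culture for any cell, so the group counts as 1 sample in a comparison of conditions. No comparison between conditions was made, and no p-value below extends beyond these cells. The p-values of variable genes set a gene's variance relative to the trend against the scatter of genes around that trend. Those of list variability and of coordination come from random draws of genes, and those of lanes from counting noise. None of these p-values measures how far a value would change with other cells, however small it is. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The count table held 25 rows with date-like names in place of gene symbols, with 0.660% of all reads; these rows were kept as they are named. Library totals held gene rows alone, and no spike-in or mitochondrially encoded rows were found, so neither served as a filter.

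Lanes were compared per cell with a chi-square test on counts, given each gene's sum over lanes and the lane totals, over genes with an expected count of at least 5 in each lane. The lanes were then summed. Cells needed at least 100000 reads and 2000 genes with a read, and all 48 cells passed. No cell lay more than 3 median absolute deviations from the median of log total count or of genes detected, so the alternatives without such cells had nothing to leave out. Counts were scaled with edgeR 4.0.16 (TMMwsp factors) to CPM, counts relative to the scaled library total, and taken as log2(CPM + 1).

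Variable genes were called with modelGeneVar of scran 1.30.0 in R 4.3.3, which compares a gene's variance over cells with a trend fitted on genes of like mean. The test was one-sided, with Benjamini-Hochberg adjustment over genes with a mean of at least 10 reads per cell and a threshold of 0.05. The variance call was tested on simulated data in which 200 well counted genes had their dispersion raised. Of these, 27% were called at 2 times the dispersion, 77.5% at 4 times and 91.5% at 8 times, and at most 0.803% of unchanged genes were called. Moderate excess spread is therefore often missed with 48 cells. Genes near the count minimum were not among the 200, so their recovery is not known. Unchanged genes called numbered 25 at 2 times the dispersion, 89 at 4 times and 66 at 8 times, and 23 where no dispersion was raised. In the simulated data, false calls thus made up a larger share of all calls than the threshold of 0.05 allows.

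Gene lists were fixed before the data were examined: 27 lists with 530 genes. A list with at least 5 tested members was compared with 10000 random lists of the same size matched on mean expression, by its median variance above the trend. Each random gene came from the 100 genes nearest in mean log2 value. The test was two-sided and adjusted over lists, and 0.0002 is the smallest p the random lists can give. Detection was counted in cells thinned to 4408953 reads, with at least 5 reads as the minimum and exact Clopper-Pearson 95% intervals.

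Cells were clustered with Ward's method on 5 principal components of the 500 genes with the largest variance above trend, with 2 to 6 clusters compared by mean silhouette and against 100 sets with shuffled values. Clusters were named from marker lists fixed before the data were examined. The cells were divided into 2 clusters, so correlations across cells and the coordination of lists are given within the larger cluster. This choice was made after the clusters were seen. No correlation of a pair of genes or scores is given over all cells, and pooled coordination is given only as an alternative. The smaller cluster was not used for correlations. Coordination within a list was its mean pairwise Spearman correlation, set against matched random lists. In simulated data the procedure recovered 4 of 4 planted lists and called 0 of 20 lists without a shared factor. The simulated values were shuffled per gene, so genes there had no background correlation. In the real cells they had, with a random median of 0.308 for ribosomal proteins. The 0 of 20 therefore sets no limit on false calls in the real cells. Correlations of Nanog, Zfp42 and Esrrb with 6 lists, and between list scores, used two-sided permutation tests with 100000 resamples. Foxa2 was constant at 0 in the larger cluster and was left out of the correlations. No doublet caller was run, and all cells were kept; cells that may hold a pair are weighed in the closing section.

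Genes were named by a rule fixed in advance: the 25 genes with the largest variance above trend among those past the test, the 10 with the lowest variance below it among genes with a mean of at least 50 reads (predicted and unnamed models left out), up to 2 highest and 2 lowest members per list, a set of pluripotency and lineage genes, and up to 5 partners of each correlated gene. Further called members of lists are named where a list is described, and 1 of them is not reported here. For the count of variable genes, alternatives covered the normalization (scran, DESeq2 1.42.0 poscounts, library size), the count filter, the pseudocount, the variance model, single lanes (with a mean of at least 5 reads, since each lane holds part of the depth), thinning, the highest cell of each gene and leaving out each cell in turn. Lists were rerun for normalization, filter, variance model and depth. Coordination was rerun for normalization, Pearson's r and genes detected regressed out, correlations for library size, genes detected and the 2 cells farthest from the median left out, and clusters for 200 and 1000 genes, for cell cycle genes left out and for genes detected regressed out. Fits on the larger cluster alone, fits without the cells that held both programs, and pooled coordination were added after seeing the data. Gene biotypes came from the RefSeq annotation of assembly GRCm38.p6, used for names only. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.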

Results

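The series asked how far gene expression varies between single ES cells kept in serum. Messenger RNA of 48 single J1 ES cells was sequenced, and all cells form 1 group, serum ES cells. Summed over lanes, a cell had 7137821 ± 1251221 reads in genes (SD, n = 48), from 4408953 to 9767245. Reads fell on 9040 ± 521 genes per cell (SD, n = 48), and 16607 of the 23284 gene rows had a read in some cell. At this depth, sampling noise was small for well expressed genes.

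Lanes of a cell were compared first, to learn whether they could be summed. Per lane, a library held from 2198523 to 4890845 reads. The chi-square index, which is 1 under pure sampling noise, was 1.00 ± 0.0160 over cells (SD, n = 48), from 0.964 to 1.05. No cell passed the adjusted threshold, and 1 cell had an unadjusted p under 0.05. Of 14712 genes tested, 0 passed by the chi-square test, and 698 (4.74%) had an unadjusted p under 0.05. The lanes of a cell agree within sampling noise and were counted as 1 sample.

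The cells fell into 2 clusters, of 35 and 13 cells. The larger one carried the markers of naive pluripotency: Esrrb was detected in 34 of its 35 cells (7 of 13 in the other), Dppa3 (Stella) in 32 (5 of 13) and Tcl1 in 28 (3 of 13), while Zfp42 (Rex1) was detected in all 48 cells. The smaller one carried the markers of primitive endoderm, the extraembryonic layer that lines the blastocyst cavity: the transcription factor Gata6, the receptor Pdgfra and the endocytic adaptor Dab2 were each detected in 13 of its 13 cells, and Gata4 in 12. Its leading genes by fold were Srgn, Ctsh, Dab2, Col4a2, Col4a1, Ankrd1, F3 and Gata6, and those of the larger cluster were Tcl1, Ncs1, Calcoco2, Tuba3a and Mest. The clusters are called naive pluripotency-like and primitive endoderm-like below; the genes that define them are not results of a comparison between them.

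The mean silhouette was 0.575 with 2 clusters, against at most 0.235 in 100 sets of shuffled values. Shuffling each gene on its own removes all correlation between genes, so a gradient of cells could exceed those sets too. The comparison therefore does not show that the clusters are separate. The first principal component held 28.3% of the variance of the clustering genes, and the second 3.59%. Pluripotency transcripts were not absent from the smaller cluster. In 8 of its 13 cells, a division made after seeing the data, 30 genes of the core and naive pluripotency lists stood at a median of 24.8% to 49.4% of their level in the larger cluster. In the other 5 cells the median was 0.325% to 0.910%. On the first principal component the 8 cells lay from 23.2 to 56.7. That is between the larger cluster (-26.25 to -6.44) and the other 5 cells (58.3 to 80.4). The trophoblast gene Cdx2, the mesoderm gene T and Zscan4c of the 2-cell-like state had 0 reads in all cells, so no cell was assigned to those states.

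**Figure D1:**
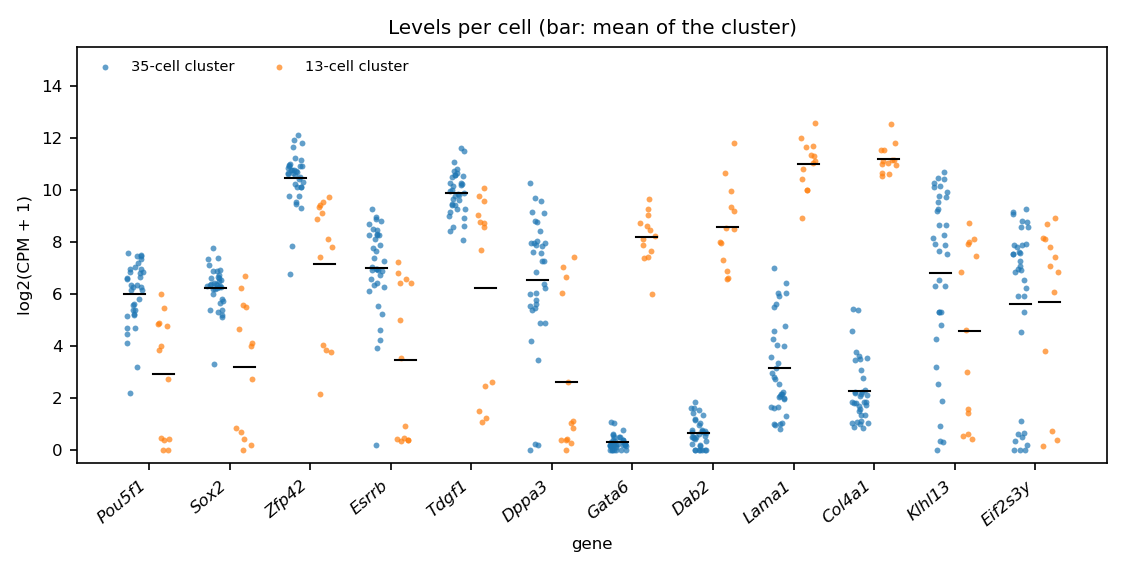
Level of 12 genes in each of the 48 cells as log2(CPM + 1), with cells of the 35-cell cluster in blue and of the 13-cell cluster in orange; bars mark the mean of each cluster. Gata6 lay at 0.30 ± 0.28 in the larger and 8.20 ± 0.95 in the smaller cluster (mean ± SD over cells), and Eif2s3y lay near 0 in cells of both.

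Which genes varied most between cells was asked next. Of 11746 genes tested, 239 (2.03%) were called as varying more than genes of like mean (scran's modelGeneVar, Benjamini-Hochberg adjusted). On simulated data this call let through more false genes than its threshold allows, so part of the 239 may be false calls. The collagen gene Col4a1 had the largest excess, and Col4a2 and the laminin chain genes Lama1, Lamb1 and Lamc1, whose products build basement membranes, were also among the 25 genes with the largest. Col4a1 had a variance of 17.2 on the log2 scale where the trend gave 4.82 (adjusted p = 2.14e-08), and Lama1 had 14.9 against 3.95 (adjusted p = 5.23e-10). Mean level over all cells was 694 CPM for Col4a1 and 682 CPM for Lama1.

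Others of the 25 were Clu, a secreted chaperone (variance 13.9, trend 2.23), F3, the tissue factor of coagulation, Glipr2, Srgn, Anxa2, Pdpn, Anxa5, P4ha1, Sfmbt2, Krt18, Btg2 and Tcf7l2. All of these had the higher mean in the primitive endoderm-like cluster, as did 19 of the 25. For Eif2s3y, among the 19, the difference was only 0.0796 log2 units. The clusters were made from the genes with the largest variance above trend, so such differences are partly built in. Klhl13, Trh, Tcl1, Morc1, Car2 and Dppa3 had the higher mean in the naive pluripotency-like cluster. Without the count filter, with scran factors and on thinned cells, Tcl1 (adjusted p from 0.0789 to 0.0843) and Anxa5 (0.0588 to 0.0754) lost their calls. With a pseudocount of 10 CPM Tcl1 lost its call (0.0939), and with the squared coefficient of variation Eif2s3y (0.245) and Morc1 (0.257) did. Of all 239 genes, 46 were higher by at least 2 log2 units in the primitive endoderm-like cells and 59 were lower by at least 2.

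A further set varied inside the larger cluster as well. Klhl13, an adaptor of a ubiquitin ligase, had a variance of 11.9 (trend 2.63, adjusted p = 3.94e-16) over all cells and 11.0 (trend 1.65, adjusted p = 3.67e-48) in the 35 cells alone. Trh, which encodes thyrotropin-releasing hormone, the Y-linked translation factor Eif2s3y (under 10 CPM in 12 of 48 cells) and the small GTPase Rab31 also passed in both fits, as did Tcl1, Morc1, Car2 and Dppa3. In all, 8 of the top 25 genes passed within the 35 cells. That fit, chosen after seeing the data, called 200 of 11454 genes, of which 137 were among the 239. Without the 8 cells that held both programs, 204 genes were called, 190 of them shared with the 239.

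Pluripotency factors differed in their spread. Zfp42 (variance 4.81, trend 0.370, adjusted p = 9.15e-192), Esrrb (7.14, trend 2.84, adjusted p = 0.00634), Dppa3 (10.1, trend 3.68, adjusted p = 0.000749) and the de novo methyltransferase Dnmt3b (2.86, trend 1.26, adjusted p = 0.0419) passed the test. Pou5f1 (4.45, trend 4.14), Sox2 (3.92, trend 3.75), Nanog (3.72, trend 5.05), Klf4 (4.62, trend 3.28) and Tbx3 (8.84, trend 5.48) did not pass, nor did Fgf5, Gata6 (12.9, trend 5.86, adjusted p = 0.0695) and Krt8 (adjusted p = 0.106). Dnmt3b lost its call with scran (adjusted p = 0.0611) or poscounts factors (0.0575), with a pseudocount of 10 CPM (0.555), without the count filter (0.108), on thinned cells (0.0923), on lane 1 alone (0.0663) and with its highest cell lowered (0.0642), but passed within the 35 cells (3.07, trend 1.07, adjusted p = 4.41e-05). Esrrb lost its call with the pseudocount of 10 CPM (adjusted p = 0.498) and with the squared coefficient of variation (0.423), while Gata6 (0.000168 and 2.71e-11) and Krt8 (0.00326 and 2.06e-17) passed under both. The trend peaks at intermediate means, where Gata6 and Krt8 lie, so a gene must vary more there to be called.

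Read in the other direction, the test called 0 of 11746 genes below the trend after adjustment (scran, with 283 at an unadjusted p under 0.05). A variance cannot fall below 0, which bounds p in this direction, and no simulated gene had its dispersion lowered. The 0 therefore does not show that no gene varied less. Farthest below the trend among well counted genes lay Oaz1 (0.260, trend 6.09), Snhg9, Uchl4, AY074887, Rpl26, Eno1, Cdk2ap1, Invs, Rpl30 and Rpl34-ps1. The count of variable genes depended on the scale: with a pseudocount of 10 CPM it was 159, and with the squared coefficient of variation it was 731, of which 99 were among the 239.

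**Figure D2:**
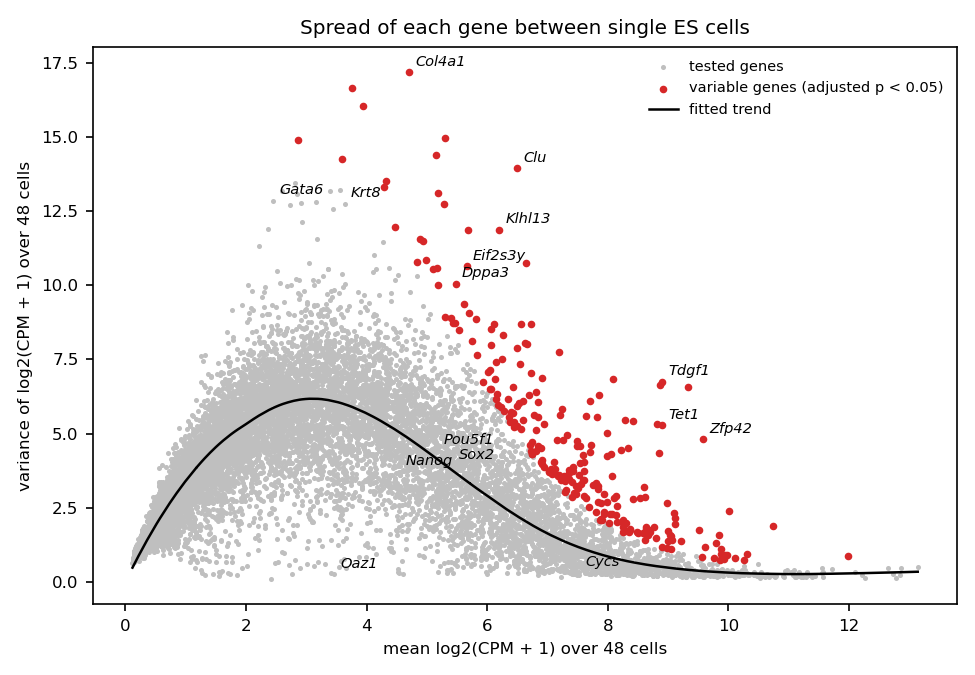
Variance of log2(CPM + 1) over 48 cells against its mean for the 11746 tested genes; the line is the fitted trend and red points are the 239 variable genes. Col4a1 lies highest at 17.2, while Nanog, Pou5f1 and Sox2 lie close to the line.

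Gene lists showed which programs varied. Of 25 lists tested, 14 had a higher median excess variance than matched random lists and 1 had a lower one. Naive pluripotency genes varied strongly: 9 of 20 tested members passed over all genes and 9 adjusted over the list alone, among them Zfp42, Tfcp2l1, Spp1, Zfp57 and Dppa3 (list adjusted p = 0.001). Of 16 primitive endoderm genes, 5 passed over all genes and 10 adjusted over the list alone (list adjusted p = 0.001); Sparc, Col4a1, Col4a2, Lama1 and Lamb1 were the 5. Core pluripotency genes had 6 of 16 members past the test and 7 adjusted over the list alone (list adjusted p = 0.0158), with Tdgf1, the Nodal co-receptor, at a variance of 6.75 (trend 0.510), followed by Utf1, Dppa4, L1td1, Lin28a and Trim28.

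Chromatin enzymes of the PRC2 and DNA methylation list varied too, with 7 of 18 past the test and 8 adjusted over the list alone (list adjusted p = 0.00312). Tet1 (variance 5.28, trend 0.509) and Tet2 (6.29, trend 0.951), which oxidise methylated cytosine, Jarid2, Mtf2, Eed, Dnmt3b and Dnmt3l were called; the maintenance methyltransferase Dnmt1 lay below the trend (1.57, trend 1.80). Within the 35 cells 3 of the 18 were called: Tet2 kept its call (3.19, trend 0.523, adjusted p = 1.1e-38) and Tet1 lost it (0.548, trend 0.306, adjusted p = 0.498). Glycolysis had 6 of 20 called, namely Slc2a3, Hk2, Ldhb, Pfkp, Bnip3 and Ldha, and 7 adjusted over the list alone (list adjusted p = 0.00954). Of 15 p53 targets, Mdm2, Ccng1 and Trp53inp1 were called, 3 adjusted over the list alone (list adjusted p = 0.001). The G2-M list had 4 of 54 called and 10 adjusted over the list alone (list adjusted p = 0.00286), with Cdk1, Top2a, Ckap2 and Plk1; the G1-S list had 3 of 43 called and 3 adjusted over the list alone (list adjusted p = 0.0213), with Mcm2, Mcm4 and Cdc6. These cell cycle calls were fragile: with scran factors or thinned cells 2 G2-M and 1 G1-S members were called, and without the count filter 1 and 1. At a mean of at least 50 reads, 5 of 53 G2-M and 3 of 43 G1-S members were called, and within the 35 cells 7 of 54 and 1 of 43.

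The remaining lists with higher spread had few called members. These were germline (1 of 14, Dnmt3l, list adjusted p = 0.001), BMP-TGFb targets (1 of 13, Skil, list adjusted p = 0.00167), trophectoderm (1 of 10, Krt18, list adjusted p = 0.00889), Polycomb target regulators (0 of 10, list adjusted p = 0.00954), imprinted genes (2 of 17, Slc38a4 and Impact, list adjusted p = 0.0196) and primed epiblast (1 of 13, Dnmt3b, list adjusted p = 0.0204). Adjusted over the list alone, the counts were 1, 1, 2, 0, 2 and 1. Ribosomal protein genes had the lower spread: 30 of 30 lay below the trend (list adjusted p = 0.001), with Rpl11 at 0.278 (trend 0.563).

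Lists that did not pass were immediate early genes (adjusted p = 0.0516), FGF-ERK targets (0.0803), oxidative phosphorylation (0.136), heat shock (0.257), cholesterol synthesis (0.283), housekeeping (0.316), mesendoderm (0.347), WNT targets (0.442), neuroectoderm (0.637) and LIF-STAT3 targets (0.828). Single members of these lists were called all the same, among them Klf6, Btg2, Etv5, Sc4mol, the transferrin receptor Tfrc, Tfcp2l1 and Lifr. The 2-cell-like list had 0 genes with enough reads and the fibroblast list had 3, so neither was tested. Within the 35 cells alone, core pluripotency (adjusted p = 0.435) and trophectoderm (adjusted p = 0.129) no longer passed, and the 5 primitive endoderm genes with enough reads there lay below random lists, at percentile 0.03. Calls were also lost with the squared coefficient of variation for core pluripotency (adjusted p = 0.710), primed epiblast (0.0918), Polycomb target regulators (0.536), p53 targets (0.0858) and G1-S (0.536); without the count filter for primed epiblast (0.382) and Polycomb target regulators (0.0962); with library size (0.0783) or thinned cells (0.0875) for G1-S; and at a mean of at least 50 reads for imprinted genes (0.0848). Calls were gained for immediate early genes in the 35 cells (0.04), with the squared coefficient of variation (0.00333) and at a mean of at least 50 reads (0.0021), and for FGF-ERK targets without the filter (0.0277) and at a mean of at least 50 reads (0.0305). Mesendoderm passed without the filter (0.0277), and oxidative phosphorylation was lower than random lists in the 35 cells (0.0265) and with the squared coefficient of variation (0.009).

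**Figure D3:**
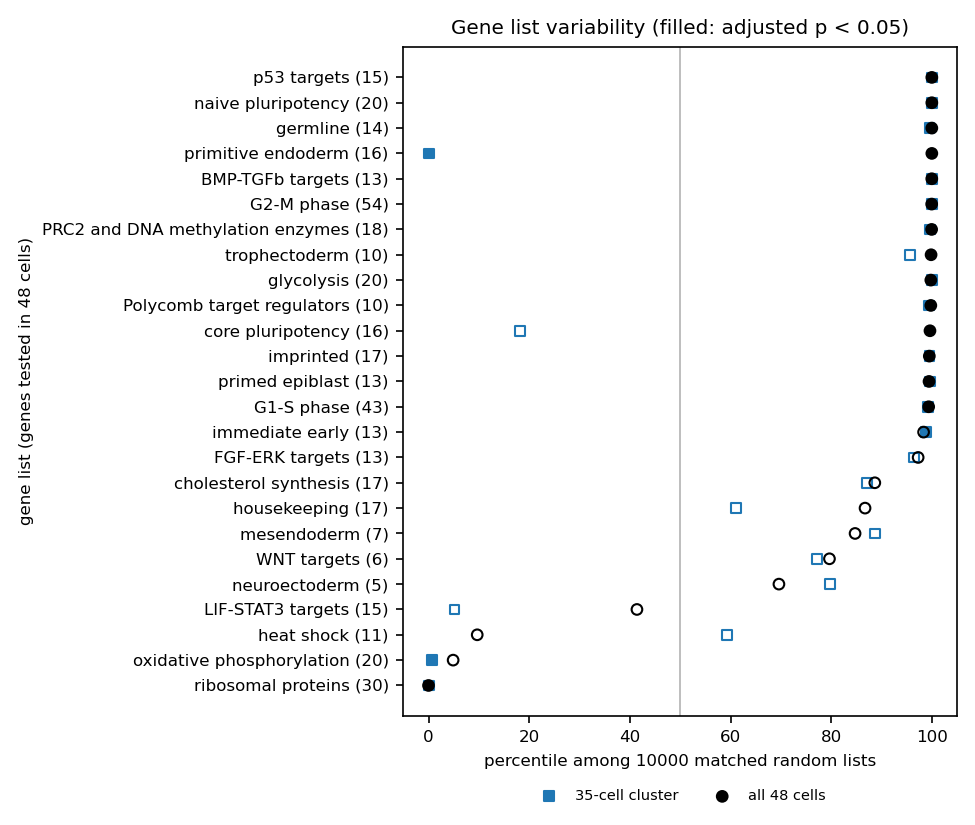
Percentile of each list's median variance above the trend among 10000 random lists matched on mean expression, for all 48 cells (circles) and the 35-cell cluster (squares); filled symbols have an adjusted p under 0.05. Primitive endoderm moves from percentile 100 to 0.03 and core pluripotency from 99.6 to 18.2.

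At a fixed depth of 4408953 reads, the core pluripotency factors were found in most cells, while lineage genes ranged from none to most of the cells. Pou5f1, Sox2, Nanog and Klf4 were each detected in 43 of 48 cells (89.6%, 95% interval 77.3% to 96.5%), Esrrb in 41, Dppa3 in 37 (77.1%, 62.7% to 88.0%) and Tbx3 in 34 (70.8%, 55.9% to 83.0%). The 5 cells without Pou5f1 all lay in the primitive endoderm-like cluster. Otx2, a factor of the primed epiblast, was detected in 35 cells, but Fgf5, its classical marker, in 3 (6.25%, 1.31% to 17.2%). Gata6 was detected in 15 cells (31.2%, 18.7% to 46.2%), of which 2 were in the naive pluripotency-like cluster. Its level in that cluster reached at most 1.11 CPM, near the read minimum, against 63.7 to 808 CPM in the other cluster. The keratin Krt8 was detected in 28 cells (58.3%, 43.2% to 72.4%), 15 of them in the naive pluripotency-like cluster.

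Germline genes were detected in part of the cells: Dazl in 13, Mael in 16, Ddx4 in 15 and Sycp3 in 25. Of 14 tested germline list genes, 11 had a mean lower by at least 1 log2 unit in the primitive endoderm-like cluster. In that cluster 0 were higher by as much. Of the 2-cell-like list, Zscan4c, Zscan4d and Zscan4f were detected in 0 of 48 cells. The exact 95% upper limit for the share of cells with each gene detected was 7.40%, and a floor of 3 cells gives 6.25%. These values hold for detection at the minimum read count and fixed depth. A cell with fewer reads, or with transcripts lost in capture, counts as negative. How reads matching several genes were counted is not stated, so 0 reads may not mean absent transcripts. The values therefore set no limit on the share of 2-cell-like cells. T and Cdx2 were likewise detected in 0 cells. Of 519 list genes with a row, 184 were detected in between 10% and 90% of cells, 153 in every cell and 59 in none.

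Genes of some lists rose and fell together over the 35 naive pluripotency-like cells. Ribosomal protein genes were the most tightly linked, with a mean pairwise Spearman correlation of 0.728 where matched random lists had a median of 0.308. This value depended on the scaling: it was 0.462 with scran factors (random median 0.0936), 0.381 with library size alone (0.0311) and 0.327 with genes detected regressed out (0.0615), and the list passed each time. Primed epiblast genes (0.225), glycolysis (0.223) and p53 targets (0.211) followed, against random medians of -0.000725, 0.0702 and -0.00117. Trophectoderm (0.153), immediate early (0.120) and G1-S genes (0.111) were linked as well; each of these 7 lists had an adjusted p of 0.000714 over 25 lists. Naive pluripotency (0.0935, adjusted p = 0.002), cholesterol synthesis (0.0830, adjusted p = 0.00125) and primitive endoderm genes (0.0853, adjusted p = 0.00167) passed at low correlations. Of the 16 primitive endoderm genes, 5 had a mean of at least 10 reads in these 35 cells, so most pairs include a gene near 0 there. How far such pairs make up the value was not measured.

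Core pluripotency genes were no more linked than random lists (0.0737, adjusted p = 0.948), and the G2-M list narrowly missed the threshold (0.101, adjusted p = 0.0546). With the number of genes detected regressed out, primitive endoderm lost its call (adjusted p = 0.144). The G2-M list passed under every other setting run, with an adjusted p of 0.000625 with genes detected regressed out or with library size alone, 0.00125 with scran factors, 0.00318 with poscounts factors, 0.0191 by Pearson's r and 0.000417 over all cells pooled. Core pluripotency passed only with all cells pooled (0.284, adjusted p = 0.000417), where the clusters themselves are compared. Germline passed by Pearson's r (adjusted p = 0.0267) and pooled (0.000417), and WNT targets with genes detected regressed out (0.0445) and pooled (0.0379).

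Partners of Nanog, Zfp42 and Esrrb were sought in the same 35 cells. Zfp42 rose with Esrrb (Pearson r = 0.849, permutation p = 1e-05, the smallest the permutations can give; Spearman rho = 0.643, permutation p = 8e-05, adjusted p = 0.0102). Tet2 rose with Esrrb (rho = 0.628, adjusted p = 0.0102), Zfp42 (rho = 0.599, adjusted p = 0.0199) and Nanog (rho = 0.533, adjusted p = 0.0357). Zfp57, which guards imprints, rose with Esrrb (rho = 0.580, adjusted p = 0.0199) and Zfp42 (rho = 0.548, adjusted p = 0.0357), and Klf2 rose with Esrrb (rho = 0.529, adjusted p = 0.0357). Lef1 (rho = -0.569, adjusted p = 0.0199) and Sall2 (rho = -0.507, adjusted p = 0.0493) were lower where Zfp42 was higher.

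These were 9 of 255 pairs, with 43 at an unadjusted p under 0.05, and their permutation p for rho ran from 8e-05 to 0.00174. Pearson's r for the pairs of Tet2 was 0.788 with Esrrb (permutation p = 2e-05, adjusted p = 0.00255), 0.731 with Zfp42 (permutation p = 6e-05, adjusted p = 0.0051) and 0.597 with Nanog (permutation p = 0.00019, adjusted p = 0.00969). For Klf2 with Esrrb it was 0.618 (permutation p = 9e-05, adjusted p = 0.00574). The pairs of Zfp57, Lef1 and Sall2 did not pass by Pearson's r, with adjusted p from 0.0747 to 0.0960. Without the 2 cells farthest from the median of the first gene, r fell to 0.678 for Zfp42 with Esrrb, 0.583 for Esrrb with Tet2, 0.516 for Zfp42 with Tet2, 0.457 for Nanog with Tet2 and 0.404 for Esrrb with Klf2. It came to 0.276 for Zfp42 with Zfp57, 0.216 for Esrrb with Zfp57, -0.319 for Zfp42 with Lef1 and -0.276 for Zfp42 with Sall2. Spearman's rho fell less, to 0.574 for Zfp42 with Esrrb, 0.572 for Esrrb with Tet2, 0.522 for Esrrb with Zfp57 and -0.492 for Zfp42 with Lef1. Of 255 pairs over the remaining 33 cells, 0 then passed by rho, with 32 at an unadjusted p under 0.05, and 2 passed by r. With genes detected regressed out, 2 pairs passed by rho and 7 by r.

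Scores of 11 lists were compared over the same cells. Of 55 pairs, only oxidative phosphorylation and ribosomal proteins moved together (Pearson r = 0.778, permutation p = 1e-05; Spearman rho = 0.797, permutation p = 1e-05, adjusted p = 0.00055; r = 0.752 without the 2 farthest cells). No pair of naive pluripotency, primed epiblast, primitive endoderm, mesendoderm or trophectoderm scores passed. Both scores fell as the number of genes detected per cell rose, with rho = -0.938 for ribosomal proteins and -0.793 for oxidative phosphorylation (permutation p = 1e-05 for each, adjusted p = 5.5e-05 over 11 scores), as did glycolysis (rho = -0.487, permutation p = 0.0034) and G2-M scores (rho = -0.486, permutation p = 0.00353), each with an adjusted p of 0.00971. After genes detected was regressed out, 0 of 55 pairs passed, with 3 at an unadjusted p under 0.05. Scores used the TMMwsp scaling and were not rerun with other factors. Cell 12, with 10291 genes detected, had a scaled total of 8002916 for 5568431 reads. Cell 3, with 8150 genes, had 5483465 for 7480064 reads. A larger scaled total lowers CPM, so the relations of scores with genes detected may come in part from the scaling, which was not tested.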

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

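The fit on the 35-cell cluster alone and the fit without the 8 mixed cells were chosen after seeing the data. The count of variable genes, 239, was 214 to 253 when each cell was left out in turn. It became 159 (118 shared) with a pseudocount of 10 CPM and 731 (99 shared) with the squared coefficient of variation; the cause was not tested. Between 191 and 270 genes were called under the other settings chosen in advance. Of the 25 genes with the largest excess, at most 2 lost their call under any such setting, and none turned below the trend. Within the 35 cells, core pluripotency turned to percentile 18.2 and primitive endoderm to 0.03 of random lists, since that fit leaves out the primitive endoderm-like cells. Calls of naive pluripotency, primitive endoderm, germline, PRC2 and DNA methylation enzymes, BMP-TGFb targets, trophectoderm, G2-M, glycolysis and ribosomal protein lists held under the normalization, filter, variance model and depth settings run for lists. The anchor gene correlations past the threshold numbered 9 by rho (8 by r), 2 (7 by r) with genes detected regressed out and 0 (2 by r) without the 2 farthest cells; the cause was not tested. The relations between list scores numbered 1, and 0 with genes detected regressed out. The partition into 35 and 13 cells was identical with 200 or 1000 genes, without cell cycle genes and with genes detected regressed out. No cell was outlying in depth, so that alternative gave no value.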

Other observations

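Of the tests below, those on carried-over reads, on dropout of single genes and on pseudogene models, and the repeat of the pair test with held-out cells, were chosen only after the result was seen. Genes named in the next paragraph were also chosen after their values were seen.

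Inside the naive pluripotency-like cluster, Klhl13, Trh and Eif2s3y had the widest excess spread. After them came the p53 targets Trp53inp1 (variance 9.63, trend 2.54, adjusted p = 3.32e-11 by scran's modelGeneVar) and Mdm2 (10.8, trend 3.78, adjusted p = 6.6e-05), the second of which encodes the ligase that degrades p53. Mdm2 ran from 0.66 to 10.78 on the log2(CPM + 1) scale over the 35 cells. The syndecan gene Sdc4 (variance 7.02, trend 0.617), the carbonic anhydrase gene Car2 (8.81, trend 2.60), the mitophagy receptor gene Bnip3 (8.22, trend 3.03) and the serine synthesis gene Psat1 (5.36, trend 1.06) were also among the 25 widest. Dppa3, Tcl1 and Tex19.1 were the naive pluripotency genes in this set.

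In 8 of the 13 primitive endoderm-like cells, pluripotency list genes stood at 24.8% to 49.4% of their level in the larger cluster. In the same 8 cells, 94 primitive endoderm genes, chosen on 4 reference cells of the 13, stood at 9.71% to 43.0% of their level in those reference cells. Cell 22, among the other 5 but not a reference cell, stood at 29.1% for these genes. The lower level of endoderm genes therefore does not set the 8 cells apart. Reads carried over from a source shared by all libraries are argued against. The highest median level of pluripotency list genes in the 13 cells was 152.1 times the lowest, where such a source would give like levels. The division into 8 and 5 cells was known before this test, and carry-over between particular libraries was not tested. Capture of a pair of cells in 1 chamber stays open and cannot be told apart from single cells in transition: the spread over 43 genes typical of the larger cluster (0.496) lay at percentile 98.6 of simulated pairs, beyond the bound set beforehand (0.476), while that over the 94 endoderm genes (0.788) lay at percentile 96.2, within its bound (0.828), but those pairs reused the cells that had defined the genes, and with held-out cells the percentile for the larger cluster's genes was 67. The mixed cells had 8988 ± 350 genes detected at equal depth (SD, n = 8), against 8725 ± 587 in the larger cluster (n = 35), 7846 ± 198 in the other 5 cells and 9756 ± 353 in simulated pairs. No biological explanation was tested, since the labels name no cell state.

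Transcripts of Y-linked genes were missing from part of the cells: in 12 of 48 (25%, exact 95% interval 13.6% to 39.6%), Eif2s3y, Ddx3y and Uty each lay under 10 CPM, while the other cells had at least 41.6 CPM over the 3 genes, with a median of 335 CPM. Independent dropout of single genes is argued against, since 11 cells had each gene under 1 CPM where 10000 shuffled sets gave at most 6. Low complexity as the sole source is argued against: genes detected ran from 8072 to 9759 in the 12 cells, against 8039 to 10291 over all cells. The Spearman correlation of Y-linked CPM with genes detected was -0.364 (permutation p = 0.0109, bootstrap interval -0.635 to -0.0454). Pearson's r on log2 values was -0.119 (permutation p = 0.422). Low complexity would give a positive value, but scaled totals tended to be larger in cells with more genes detected. That lowers CPM there, so the negative sign alone does not decide the question. The 12 cells lay in both clusters, 9 in the larger and 3 in the smaller. Loss of the Y chromosome in part of the culture is a hypothesis these data may fit; cells of another line were not tested for, and no biological explanation was tested.

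Gene models with very low spread were enriched for annotated pseudogenes. Among the 584 genes with the lowest variance relative to the trend, 41 (7.02%) were pseudogene models, against 0.583% of all 11673 matched genes, a ratio of 12.05. That ratio is consistent with reads shared with an abundant parent gene, which would carry the parent's steady level into the copy and lower the apparent level of the parent. Levels of these pseudogene models are therefore uncertain. The shares were not matched on mean level. Whether Oaz1, Eno1 and Rpl26, which also lay far below the trend, share reads with such models was not tested, nor was any biological explanation.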
